A study of Oryzias latipes with 24 samples.

How the data were processed

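RNA was measured in sorted cells of medaka (Oryzias latipes) on 24 Agilent arrays of 60-nucleotide probes. Per the labels, germ cells were sorted on the fluorescence of an olvas-EGFP transgene and gonadal somatic cells on that of a sox9b-DsRed transgene, RNA was extracted from the sorted cells, and the whole amount was labelled with Cy3 by a low-input 1-colour protocol. The samples came from XX and XY animals at stages 33 and 35, which gave 8 groups with 3 independent biological replicates each, per the series description. A p-value of the fit over all 24 arrays therefore measures a difference against the spread between such replicates, pooled per probe over the 8 groups.

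The deposited scanner files hold, per spot, a processed signal that is an intensity on a linear scale. Per the file headers the authors' software, Agilent Feature Extraction, subtracted background, detrended the array in space and replaced dim spots by surrogate values, with no scaling between arrays. The version is 9.1 in the submitters' processing notes and 9.5.3.1 in the file header. The deposited files also hold the raw spot brightness and the local background, each an intensity, and 0 or 1 flags per spot (other), per the file headers. The deposited table of processed values was checked against the scanner files: 680808 of its 680808 values equalled the mean processed intensity over a probe's spots within 0.1%, so it carries no scaling between arrays either.

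Each array held 43803 spots outside the controls, which were averaged to 28367 probes, of which 15436 had 2 spots. Those probes carried 25865 distinct sequences. Spots marked as outliers by the authors' software were left out. The mean intensity of each probe was scaled so that the 75th percentiles of all arrays were equal, values under 1 were set to 1, and log2 was taken. A probe was tested when it was well above background, as marked in the deposited files, on all 3 arrays of at least 1 group, and had a value in every group. That left 22115 probes.

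The comparisons were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 24 arrays, moderated by eBayes, two-sided, and adjusted by Benjamini and Hochberg over all probes tested within each comparison. A probe was called at an adjusted p under 0.05. Signed differences are given as the side named first minus the other side: germ minus somatic, XX minus XY, and stage 35 minus stage 33. An interaction is the difference between 2 such differences. The comparisons of cell types, sexes within each population, and stages within each cell type, with 3 of the interactions, were fixed before the data were examined. The interaction of stage with cell type and that of sex with cell type at stage 33 were added afterwards.

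No probe could be tied to a gene. The probe names are serial numbers or clone names, all descriptions read unknown, and 0 of the probe names matched any of the 26845 rows of the reference gene table. The 27 gene lists fixed beforehand, with 780 members, therefore matched 0 probes, and neither the list tests nor the genes fixed by symbol could be given. The rule for the probes named in the text was fixed for gene symbols. It was applied to probe names instead, after it was seen that the files hold no symbols: among called probes with at least a 2-fold change and no overlap between the arrays of both sides (the overlap and the background conditions were not asked of interactions), the 2 largest changes in each direction, with the brighter side well above background on all of its arrays. Where a side was not well above background on all of its arrays, the probe was ranked by a reduced change, called a bound here. That bound sets each array's value on the dim side to the highest of that value and the lowest well-above-background signal on that array, and is written as at least so many fold. It is no strict limit, since probes over that lowest signal could also fail to be well above background. On the stage 33 XX germ cell arrays dola:728 lay at 1.36 to 2.04 and was above background on 0 of 3. The lowest signals there were 0.52, 0.70 and 1.18. Nor does the bound cover the spread between replicates. Where no dim value lay under that lowest signal, the bound equals the fitted change, which is then given as fitted.

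The 24 arrays lie on 6 slides of 4 arrays, and each slide holds 1 sex and 1 replicate number. Position 1 on each slide held stage 33 germ cells, position 2 stage 35 germ cells, position 3 stage 33 somatic cells and position 4 stage 35 somatic cells. The slides were scanned on 5 days, all 3 XX slides before all 3 XY slides. Comparisons of cell type and stage lie within slides, whereas sex cannot be told apart from slide and scan run. The background of the arrays with XX replicates 1 and 2, whose headers carry the same slide code, correlated at 0.004 to 0.104 across spots, so these are not rescans of 1 slide.

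The calling was tested on simulated data with 200 changed probes per comparison, 67, 67 and 66 of them by 1.5-fold, 2-fold and 4-fold. Each probe otherwise had 1 mean for all groups, and a spread taken from these arrays over all groups or per cell type. The simulated arrays therefore held none of the other differences between the real groups. The shares of unchanged probes below depend on the number of changed probes and need not hold for the real calls. With 1 spread per probe for all arrays, 2.44% to 8.02% of the calls per comparison were unchanged probes. With a separate spread for germ cell and somatic cell arrays that share rose to 41.9% and 39.6% in the sex comparisons of somatic cells at stages 33 and 35, 39.1% in the stage comparison of somatic cells and 45.2% in their sex by stage interaction. It was 2.26% to 7.19% in the comparisons within germ cells, 9.60% between the cell types, and 8.33% to 12.9% in the interactions across cell types. In a fit of the arrays of 1 cell type alone it was 1.25% to 7.01% in every comparison within a cell type. The simulated groups of a cell type shared 1 spread, so these shares do not cover the unequal spreads of the real groups. Their median SD per probe ran from 0.10 to 0.22 in germ cells and from 0.18 to 0.32 in somatic cells (log2). Of simulated 2-fold sex differences in somatic cells at stage 33, 64.2% were recovered over all arrays and 37.3% over the somatic arrays alone.

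The alternatives tried were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, the deposited table without scaling, replicate number, slide or scan day as a block, a fit of the compared arrays alone, a trended and robust prior, and leaving out each array in turn. Added after the data were examined were 1 probe per distinct sequence, probes well above background on all arrays, a fit of the arrays of 1 cell type, and removal from each array of a smooth trend (lowess, span 0.3) on the GC content of the probes. Slide and scan day entered as fixed blocks where a comparison lies within slides, and as random blocks in the sex comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. The number of arrays limits the precision: 3 arrays against 3 make only 10 splits, so that a permutation of labels cannot give a p under 0.1.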

Results

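Expression was measured in sorted germ cells and sox9b-expressing gonadal somatic cells of XX and XY medaka at stages 33 and 35, a time that the series title places in gonadal sex differentiation. Each of the 8 combinations had 3 arrays. On the 12 germ cell arrays 71.9% ± 4.18 (SD, n = 12) of the 28367 probes were well above background, with a range of 63.9% to 79.2%. On the 12 somatic cell arrays the share was 61.4% ± 3.36 (SD, n = 12), with a range of 56.0% to 66.8%. The 75th percentile of the unscaled intensity ran from 92.1 to 237.7 on germ cell arrays and from 44.2 to 100.6 on somatic arrays. The 100 brightest probes took 23.6% ± 1.58 (SD, n = 12) of the signal in germ cells and 39.8% ± 1.87 (SD, n = 12) in somatic cells. Each of these 3 measures differed between the cell types, with a two-sided permutation p of 1e-05, the smallest that 100000 resamples give, and a Benjamini-Hochberg adjusted p of 1e-05. The labels were shuffled over all 24 arrays and not within slides. Position on the slide followed cell type, so its effect on these measures cannot be told apart.

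Pairs of arrays from 1 group correlated at 0.964 to 0.996 across the 22115 tested probes, with a median of 0.987. Arrays of the same cell type and stage but the other sex correlated at a median of 0.983, those of the same cell type and sex but the other stage at 0.960, and germ cell with somatic arrays at 0.641. These correlations are across probes, which are not independent replicates. The median SD per probe between replicates, on the log2 scale, was 0.13 in XX and 0.10 in XY germ cells at stage 33, 0.22 and 0.13 at stage 35, 0.26 and 0.18 in somatic cells at stage 33, and 0.32 and 0.19 at stage 35. It was thus larger in somatic than in germ cells of the same sex and stage, and larger in XX than in XY in all 4 populations, where sex and slide cannot be told apart.

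**Figure D1:**
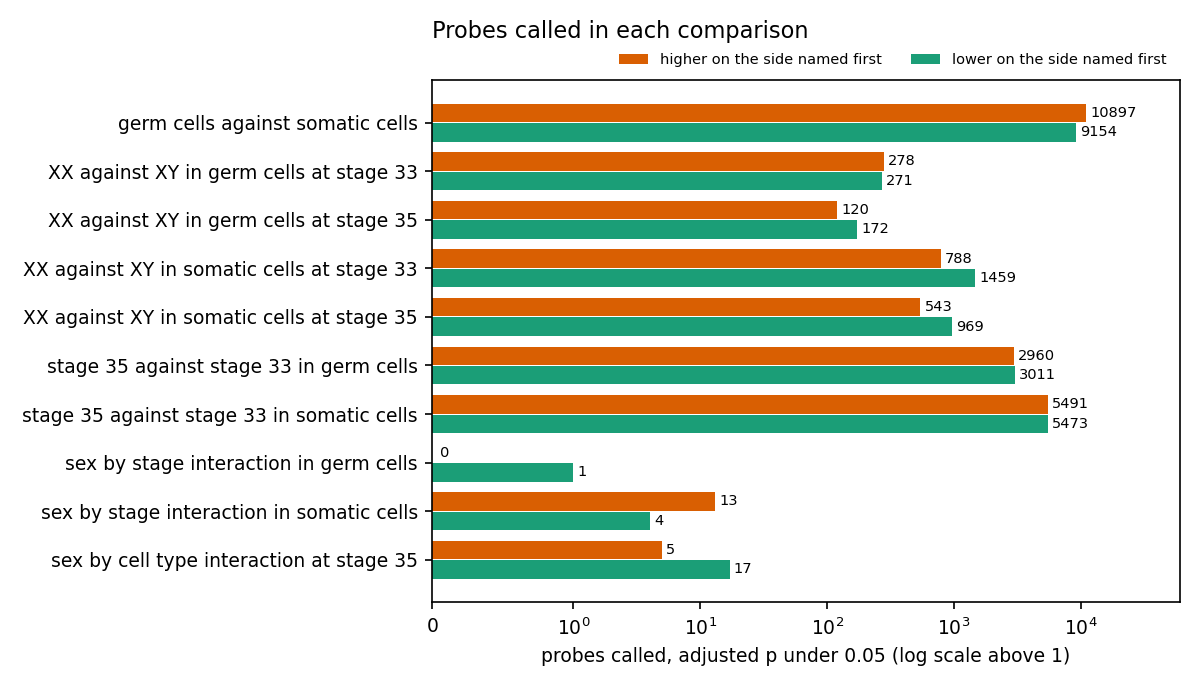
Bars give the number of probes called at an adjusted p under 0.05 in each of the 10 comparisons fixed beforehand, those higher and those lower on the side named first, on an axis that is linear from 0 to 1 and logarithmic above. Calls run from 20051 between germ and somatic cells to 1 in the sex by stage interaction of germ cells.

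The first comparison asked which probes distinguish the sorted populations. Between germ and somatic cells 20051 of the 22115 probes were called, 10897 higher in germ cells and 9154 higher in somatic cells, and 13138 changed at least 2-fold. The direction of the majority rested on the processing: germ cells were higher in 54.3% of the calls, against 33.8% after normexp background correction, 44.3% without the filter on dim probes and 75.3% without scaling between arrays. Under normexp 15263 of the 20051 calls were kept in the same direction. Of all probes, 12742 were well above background on all 24 arrays. Another 1348 were so on every germ cell array and no somatic array, and 272 on every somatic array and no germ cell array.

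On germ cell arrays dola:6085 had a mean log2 signal of 11.71 ± 0.16 (SD, n = 12), and it was well above background on 0 of the 12 somatic arrays. By the bound set out above, which is no strict limit, it was at least 804-fold higher in germ cells (adjusted p 1.06e-23). Likewise dola:25607 was at least 769-fold higher in germ cells and was above background on 0 of 12 somatic arrays. In the other direction dola:16497 was at least 5240-fold lower in germ cells, with a mean of 13.69 ± 0.69 (SD, n = 12) in somatic cells and a signal above background on 2 of 12 germ cell arrays. The probe dola:13074 was at least 4430-fold lower in germ cells, at 13.37 ± 0.54 (SD, n = 12) in somatic cells, also above background on 2 of 12 germ cell arrays. Within each of the 6 slides, at least 99.7% of the probes with at least a 2-fold change had the sign of the comparison over all slides. These probes were picked over the same arrays, so a high share follows from the choice and is no separate test.

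The comparison of XX with XY was made in each population at each stage, to find sex differences during gonadal sex differentiation. In germ cells 549 probes were called at stage 33, 278 higher in XX and 271 lower, and 177 changed at least 2-fold. With single arrays left out the count ran from 131 to 387, and under normexp background correction it was 455, with 246 of the 549 calls kept in the same direction. At stage 35 the germ cells had 292 calls, 120 higher in XX and 172 lower, with 96 at least 2-fold, and 78 to 381 calls with single arrays left out. In somatic cells 2247 probes were called at stage 33, 788 higher in XX and 1459 lower, with 464 at least 2-fold, and 1512 at stage 35, 543 higher in XX and 969 lower, with 330 at least 2-fold. With single arrays left out these counts ran from 774 to 2415 and from 407 to 2886. Normexp background correction left 139 calls in germ cells at stage 35, and 236 and 191 in somatic cells at stages 33 and 35. The balance of higher and lower calls rested on the processing. Without a trend on probe GC content 711 were higher and 828 lower in somatic cells at stage 33, and 112 higher and 97 lower in germ cells at stage 35. Without scaling between arrays 4 were higher and 58 lower in germ cells at stage 33, and 2 higher and 37 lower in somatic cells. The somatic counts depended on a spread shared with the germ cell arrays, which varied less at the same sex and stage: fitted on the somatic arrays alone, 51 probes were called at stage 33 and 46 at stage 35. Fitted on the germ cell arrays alone, 2026 and 1292 probes were called. In data simulated with 200 changed probes and a separate spread per cell type, the fit over all arrays called 93 unchanged probes among 222 somatic calls at stage 33 and 78 among 197 at stage 35. The share of unchanged probes depends on the number changed, so it does not carry over to the real calls. As the order of the counts turned with the arrays fitted, the larger somatic count is not a measured difference in the number of sex-dependent probes. All XX slides were scanned before all XY slides, and no slide held both sexes, so that within-slide values do not exist for these comparisons and sex cannot be told apart from slide and scan run.

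At stage 33 the germ cells of XX animals exceeded those of XY animals at dola:20434 by 3.11 (log2; SE 0.57, adjusted p 0.00674), with means of 6.52 ± 0.11 (SD, n = 3) and 3.41 ± 0.59 (SD, n = 3). At dola:8876 they exceeded them by 2.38 (SE 0.30, adjusted p 0.000224). The probe olteno51_j13 (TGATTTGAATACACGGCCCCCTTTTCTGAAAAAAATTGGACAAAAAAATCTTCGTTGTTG) was lower in XX germ cells by a fitted 30.2-fold (SE 0.43 on the log2 scale, adjusted p 3.83e-06), at 6.83 ± 0.10 (SD, n = 3) in XY and above background on 1 of 3 XX arrays. Likewise dola:14722 (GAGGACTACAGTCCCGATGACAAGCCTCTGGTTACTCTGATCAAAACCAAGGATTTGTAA) fell by 2.92 in XX relative to XY (SE 0.21, adjusted p 3.41e-07), with means of 3.07 ± 0.17 (SD, n = 3) and 5.99 ± 0.20 (SD, n = 3).

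At stage 35 olteno51_j13 was at least 24.9-fold lower in XX germ cells and above background on 0 of 3 XX arrays (adjusted p 4.16e-06). A second probe, olteno54_h09_1, was lower by a log2 difference of -2.68 (SE 0.31, adjusted p 0.000108). Of the probes higher in XX germ cells, dola:8876 differed by 2.28 (SE 0.30, adjusted p 0.000412), and olebno15_p05_2 was at least 6.63-fold higher (adjusted p 0.0446). The call of olebno15_p05_2 ended under 10 of the other settings, among them leaving out any of 5 of the 6 arrays, with adjusted p of 0.00713 to 0.339 over all of them.

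In somatic cells at stage 33, dola:8876 was higher in XX by 2.04 (SE 0.30, adjusted p 0.00076) and dola:20434 by 1.89 (SE 0.57, adjusted p 0.0411). Neither was called in the fit of the somatic arrays alone. The call of dola:20434 ended under 13 of 19 other settings, among them leaving out any single array of the comparison, and that of dola:8876 under 2. Over the other settings that tested them the adjusted p ran from 7.15e-05 to 0.104 for dola:8876 and from 0.0230 to 0.188 for dola:20434. The probe dola:12476 (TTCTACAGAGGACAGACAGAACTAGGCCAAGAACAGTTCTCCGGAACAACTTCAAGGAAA) was lower in XX by a fitted 10.2-fold (SE 0.19 on the log2 scale, adjusted p 3.78e-09), at 6.35 ± 0.12 (SD, n = 3) in XY and above background on 2 of 3 XX arrays. It was above background on 0 of the 12 germ cell arrays. The probe dola:14722 was at least 9.23-fold lower in XX somatic cells (adjusted p 5.22e-10) and above background on 0 of 3 XX arrays. Its call ended under normexp background correction, where the log2 difference was -0.53 against -4.20, and its adjusted p ran from 1.52e-10 to 0.0574 over the other settings that tested it.

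Stage 35 somatic cells had dola:12476 lower in XX again, by a log2 difference of -3.08 (SE 0.19, adjusted p 1.15e-08). At the same stage dola:25381 was at least 19.5-fold lower, at 6.21 ± 0.22 (SD, n = 3) in XY and above background on 0 of 3 XX arrays. Higher in XX were dola:16504, at least 12.2-fold with 0 of 3 XY arrays above background, and dola:16568, by a fitted 8.07-fold with 1 of 3. The call of dola:16568 ended in the fit of the somatic arrays alone, and its adjusted p ran from 0.00104 to 0.245 over the other settings that tested it.

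**Figure D2:**
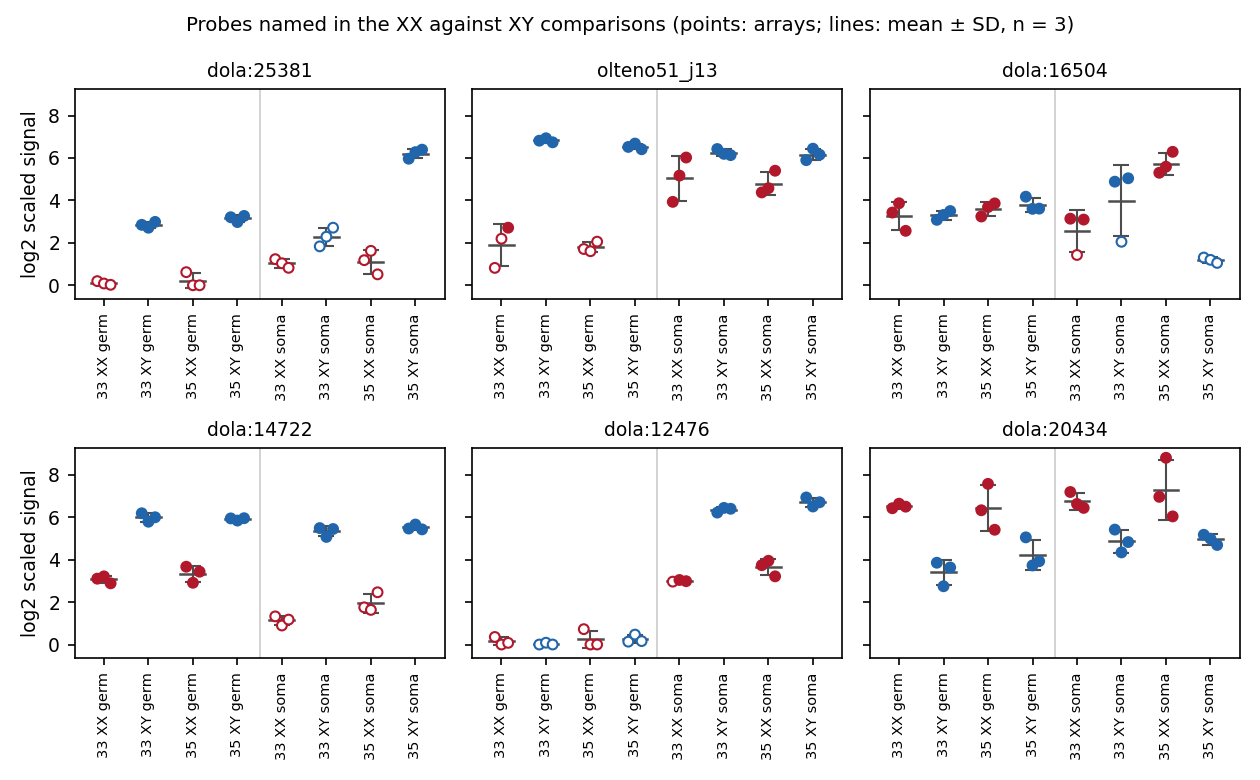
Points are the log2 scaled signals of the 24 arrays at the 6 probes with the largest changes among those named in the sex comparisons, filled where well above background, and lines give the mean and SD of each group (n = 3). XY arrays exceed XX arrays in all 4 populations at dola:14722 and olteno51_j13, and XX exceed XY at dola:20434, while dola:12476 stays under the background in germ cells.

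Across the 4 populations 3478 probes were called in at least 1 sex comparison, and 69 in all 4. Of those 69, 68 had the same direction in all 4, with 30 higher in XX and 38 lower. The 68 probes had 63 distinct sequences. The sex differences correlated across probes at 0.63 between the stages in germ cells and 0.52 between the stages in somatic cells. Between germ and somatic cells they correlated at 0.48 at stage 33 and 0.40 at stage 35. The populations share slides, so these comparisons are not independent of each other.

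The XX minus XY difference also followed the GC content of the probes. It correlated with GC content at -0.26 in germ cells at stage 33, -0.25 at stage 35, -0.23 in somatic cells at stage 33 and -0.20 at stage 35, across probes. The log2 signal of the 3 XX slides changed on average by -0.13, -0.13 and -0.03 per 10 percentage points of GC content relative to the mean of all arrays, and that of the XY slides by 0.13, 0.06 and 0.09. The slide means differed by -0.19 between the sexes, with an exact two-sided permutation p of 0.1, the smallest that 3 slides against 3 allow. Without that trend the sex comparisons called 420 and 209 probes in germ cells at stages 33 and 35, and 1539 and 1145 in somatic cells.

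**Figure D3:**
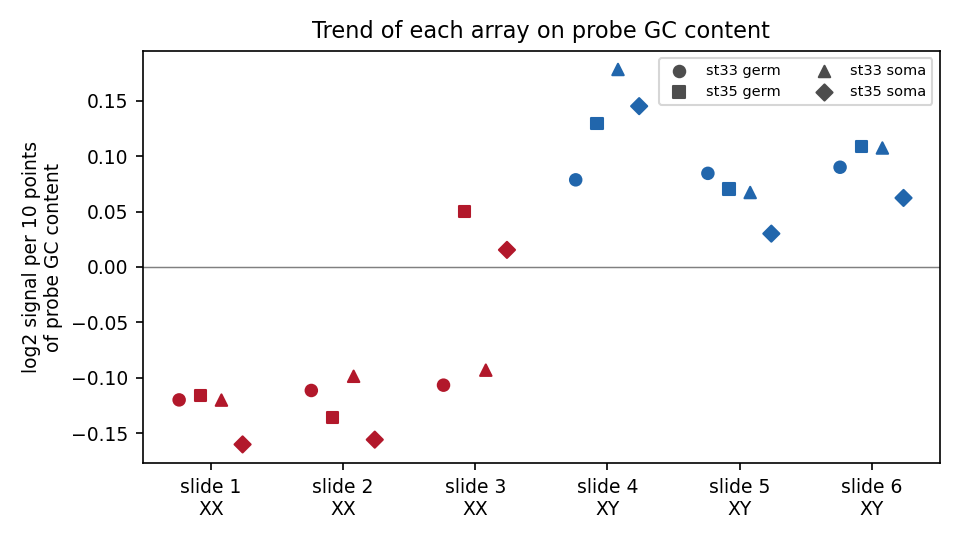
Points give, for each array, the slope of the log2 signal on the GC content of the probes relative to the mean of all arrays, by slide, with a symbol per population. All 12 XY arrays lie above 0, and all XX arrays lie below it but the stage 35 arrays of slide 3, at 0.05 and 0.02.

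The comparison of stages asked how each cell type changed from stage 33 to stage 35. In germ cells 5971 probes were called, 2960 higher at stage 35 and 3011 lower (205 and 763 without scaling between arrays), and 646 changed at least 2-fold, 238 of them higher. In somatic cells 10964 were called, 5491 higher and 5473 lower, and 2916 changed at least 2-fold, of which 2087 were higher at stage 35 and 829 lower. The somatic calls were 2207 higher and 2672 lower without scaling between arrays, and 4527 and 6925 under quantile normalization. In data simulated with 200 changed probes and a separate spread per cell type, 99 of 253 somatic calls and 12 of 167 germ cell calls were unchanged probes, shares that do not carry over to the real calls. Fitted on the arrays of the stage comparison alone, 8637 probes were called in somatic cells and 9267 in germ cells, so the order of the total counts of the cell types rests on the spread used. Within single slides, 98.1% to 99.8% of the germ cell probes with at least a 2-fold change and 96.4% to 99.2% of the somatic ones had the sign of the comparison over all slides. Here too the probes were picked over the same arrays, so the shares are no separate test. Position on the slide followed stage and cell type on all 6 slides, so an effect of position cannot be told apart from these comparisons.

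The germ cell probe with the largest measured rise was dola:6846, which rose by 4.58 (SE 0.28, adjusted p 6.84e-09), from 3.68 ± 0.48 (SD, n = 6) to 8.25 ± 0.34 (SD, n = 6). A further probe, dola:728, was at least 16.2-fold higher in germ cells at stage 35, with 0 of 6 stage 33 arrays above background. Lower in germ cells at stage 35 were dola:13510, which fell by 3.63 (SE 0.31, adjusted p 2.84e-07), and dola:6592, at least 8.27-fold lower. The somatic means of dola:728, dola:13510 and dola:6592 moved in the same direction, and were higher than the germ cell means at both stages. For dola:13510 they fell from 12.37 (XX) and 10.92 (XY) to 8.12 and 7.28. In contrast, dola:6846 was above background on no somatic array. In somatic cells dola:13467 rose by 8.49 (SE 0.24, adjusted p 8.23e-15), from 4.28 ± 0.57 (SD, n = 6) to 12.77 ± 0.56 (SD, n = 6), and dola:10902 was at least 298-fold higher at stage 35. The somatic probes dola:6566 and dola:2088 were at least 29.0-fold and 28.5-fold lower at stage 35. Germ cell means of dola:6566 fell as well, from 7.22 (XX) and 6.80 (XY) to 3.94 and 4.40.

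The changes with stage in the cell types correlated across probes at 0.08. Of the probes called in both, 1353 had the same direction and 1881 opposite directions, where lists of these sizes drawn independently would share 1480 in the same direction. The difference between the changes of the cell types, tested as an interaction, was called at 9684 probes. Of the 2087 somatic probes that rose at least 2-fold, 1794 (86.0%) had a called interaction, against 43.8% of all probes tested. Among the 238 germ cell probes that rose at least 2-fold, 156 had one. The interaction holds the change by which these probes were picked, so a high share follows in part from the choice.

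**Figure D4:**
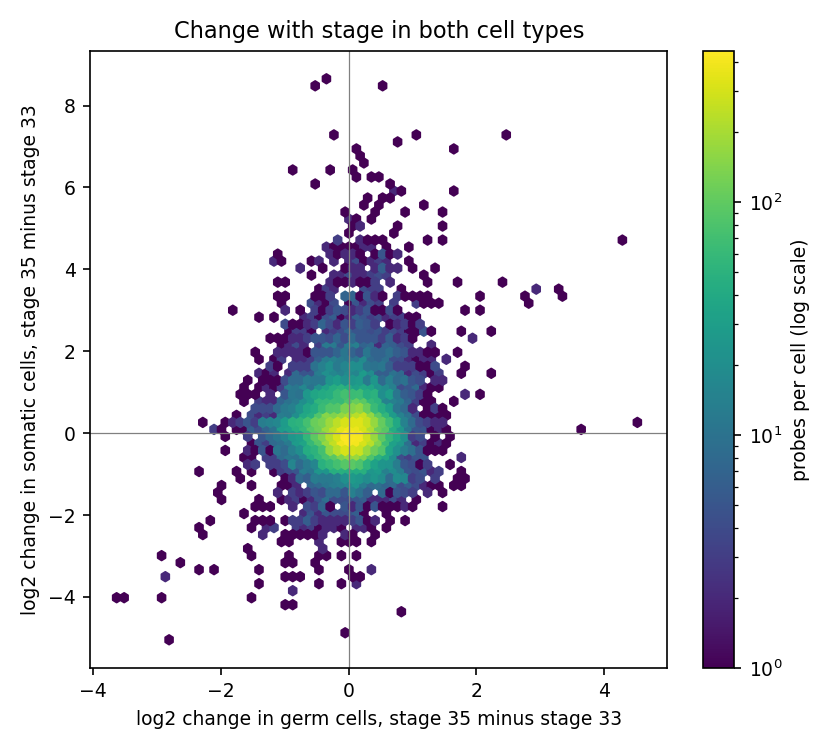
Each cell counts, on a logarithmic colour scale, the tested probes by their log2 change from stage 33 to stage 35 in germ cells (horizontal) and in somatic cells (vertical). The changes in somatic cells spread wider than those in germ cells, and most large somatic changes lie near 0 in germ cells.

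The remaining comparisons asked whether sex differences themselves differed. Between stages they differed at 1 probe in germ cells, with 423 at an unadjusted p under 0.05, and at 17 probes in somatic cells, with 1693 at an unadjusted p under 0.05. Between the cell types they differed at 22 probes at stage 35 and at 13 at stage 33. The 17, 22 and 13 probes had 16, 19 and 12 distinct sequences. In data simulated with a separate spread per cell type the fit over all arrays recovered 75.8% of 4-fold and 23.9% of 2-fold interactions of sex and stage in germ cells. It thus missed most 2-fold interactions. A fit of the germ cell arrays alone recovered 87.9% and 49.3% in the same data. In somatic cells the fit over all arrays recovered 78.8% of 4-fold interactions, and 66 of its 146 calls in those data, with 200 changed probes, were unchanged probes. With 1 spread per probe for all arrays, 3 of its 80 calls there were unchanged probes. With no changed probe it called 42 under a separate spread per cell type and 0 under 1 spread for all arrays.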

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

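The interaction of stage with cell type, that of sex with cell type at stage 33, the splits of the 6 slides for the interactions with sex, and the size of sex differences left without the GC trend are tests chosen after results had been seen. The remaining tests of this part were chosen before the result that each measures was seen. The size of an interaction with a group under the background depends on the value given to that group and is no bound. For the splits of an interaction the additive effects of its factors were removed first. The splits of arrays move single arrays, whereas sex was set by slide, and the 6 slides have only 10 splits, too few for a share under 0.05.

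Sex differences differed between the stages at 1 probe in germ cells, dola:3746, with an interaction of -1.87 (log2, adjusted p 0.0440). It was above background on 2 of the 6 XX and 2 of the 6 XY germ cell arrays, so it lies close to the background there. In 6 of 100 splits of the germ cell arrays, the real one included, at least 1 probe was called, up to 3, so chance cannot be excluded for this result. By slide, 1 of 10 splits called as many, the real one, with 0 in the highest other. With slide as a block 0 probes were called.

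In somatic cells the sex difference changed with stage at 17 probes, with 16 distinct sequences. The 2 largest fitted interactions in each direction were dola:16504 at 5.98 (adjusted p 0.00368), dola:16568 at 4.25 (0.0376), dola:25381 at -3.85 (1.83e-05) and dola:383 at -2.26 (0.0376). The calls of dola:16568 and dola:383 ended under 13 other settings each, slide as a block among them, with adjusted p from 0.000858 to 1 and from 0.00406 to 1 over those that tested them. That of dola:16504 ended under 2 (7.53e-06 to 0.606) and that of dola:25381 under 1 (4.91e-06 to 0.606). Their sizes rest partly on values under the background: dola:16504 was above it on 0 of 3 stage 35 XY somatic arrays and dola:16568 on 1 of 3, dola:25381 on 0 of 3 in each of the other somatic groups than stage 35 XY, and dola:383 on 0 of 6 stage 33 somatic arrays. With slide as a block 6 probes were called, and with single arrays left out 8 to 56. In 29 of 100 splits, the real one included, as many probes were called, and the highest other split called 510, so chance cannot be excluded for this count. By slide, 3 of 10 splits called as many, with 48 in the highest other, which set XX replicates 1 and 3 and XY replicate 3 against the rest. Such counts may come from a structure among the somatic arrays, which was not tested.

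Between germ and somatic cells the sex difference at stage 35 differed at 22 probes, with 19 distinct sequences. Among them were dola:12476 at 3.07 (adjusted p 1.49e-05), olecno35_l06 at 2.45 (2.05e-05), dola:16504 at -4.74 (0.0212) and dola:13662 at -3.43 (0.000107). The call of dola:16504 ended under 7 other settings, among them leaving out any of 5 of the 6 germ cell arrays, with adjusted p from 0.00119 to 0.757 over the other settings that tested it. Those of the other 3 ended under 1 setting each. For dola:12476 and dola:13662 it was normexp background correction, with interactions of 0.97 and -0.51. For olecno35_l06 it was the deposited table without scaling, at 2.66. The probe dola:12476 was above background on 0 of 12 germ cell arrays and dola:13662 on 0 of 12 somatic arrays, so their interactions show a sex difference in 1 cell type and no measured one in the other. On the 3 stage 35 XY somatic arrays dola:16504 was above background on 0. With single arrays left out the count ran from 12 to 129. In 4 of 100 splits of arrays as many were called, the real one included, and the highest other split called 405. By slide, 2 of 10 splits called as many, and that of XX replicates 1 and 3 with XY replicate 3 called 26. At stage 33 the difference was called at 13 probes, with 12 distinct sequences, among them dola:12476 at 3.47, dola:12622 at 2.70, olteno51_j13 at -3.71 and dola:13662 at -3.15. There 1 of 100 splits of arrays, the real one alone, called as many, and the highest other split called 4. By slide, 1 of 10 splits called as many, the real one, with 1 in the highest other. With single arrays left out the count ran from 11 to 48, and under normexp background correction 19 were called, with 6 of the 13 kept. On XX arrays of stage 33 dola:12622 was above background on 0 of 3 somatic and olteno51_j13 on 1 of 3 germ cell arrays. The calls of dola:12622 and olteno51_j13 ended under 2 other settings each and those of dola:12476 and dola:13662 under 1. Normexp background correction was among these for dola:12622, dola:13662 and dola:12476, with interactions of 0.10, -0.09 and 1.23.

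The change with stage differed between the cell types at 9684 probes, 4757 with the more positive change in germ cells and 4927 with the more positive change in somatic cells. This balance rested on the processing: the change was more positive in germ cells in 49.1% of the calls, against 58.0% under quantile normalization, 61.0% among probes above background on all arrays and 37.9% without scaling between arrays. The 2 largest as fitted in each direction were dola:12271 at 5.19, dola:2088 at 4.83, dola:2589 at -9.03 and dola:10902 at -8.98. These sizes rest partly on values under the background: dola:12271 was above it on 1 and dola:10902 on 0 of 12 germ cell arrays, dola:2589 on 1 of 6 stage 33 somatic arrays and dola:2088 on 2 of 6 stage 35 somatic arrays. Only the real split among 100 called as many (1 of 100), with 2 in the highest other, a share under 0.05. The shuffled splits moved arrays across slides and held the interaction itself as spread within groups, which lowers their counts. The share therefore does not exclude chance outright.

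For the other comparisons, 1 of 100 splits, the real one, called as many probes. Between germ and somatic cells these were 20051 probes against 13825 in the highest other split, and between stages 5971 against 727 in germ cells and 10964 against 8030 in somatic cells. Each share was under 0.05. These splits too moved arrays across slides and held the real difference as spread within groups, so the shares do not exclude chance outright. The sex comparisons have 10 splits of 6 arrays each, too few for a share under 0.05, and the real one ranked first in each (1 of 10). The real and the highest other counts were 549 and 1 in germ cells at stage 33, 292 and 1 at stage 35, 2247 and 121 in somatic cells at stage 33, and 1512 and 177 at stage 35.

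The first pattern weighed is the set of 68 probes, with 63 distinct sequences, that had a sex difference of the same direction in all 4 populations. Of the 10 splits of the 6 slides into 3 and 3, the split by sex gave 68 such probes and every other split gave 0, but all XX slides were scanned before all XY slides. A difference between slides or scan runs and a difference between the sexes therefore cannot be told apart for these probes. GC content was set down beforehand as the cause if under 50% of the probes were still called in all 4 populations without the GC trend, and 48.5% were, 33 of 68, so that outcome was met. Counting probes outside the 68 as well, 47 were called the same way in all 4 populations without the trend. The sizes changed less than the calls. All 68 kept their sign, and over the 35 probes no longer called in all 4 populations the median size of the mean log2 difference fell from 0.66 to 0.52, with a median SE of 0.13 before and 0.14 after. Over all 68 a median of 88.5% of the size was left, with a 25th percentile of 78.8%, which does not settle how much of the differences the trend gives. A trend with GC content may account for part or all of the lost calls. A sex difference and a slide or scan difference stay open as well, and no test here separates them.

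The second pattern is the 94 probes at least 2-fold higher at stage 35 in both cell types, where independent lists of these sizes would share 22.5. An excess was not particular to shared rises: 43 probes were at least 2-fold lower in both, against 15.3, and 29 were higher in germ cells and lower in somatic cells, against 8.92. Another 47 were lower in germ cells and higher in somatic cells, against 38.5. If somatic RNA carried into the germ cell sort were the source, the rise in germ cells would need a median of 13.9% of the somatic signal. The 5th percentile of the ratio of germ to somatic signal over the 500 brightest somatic probes was 0.318%, and 92 of the 94 probes needed more than that, which argues against such carry-over. RNA of 1 other source in both sorts would give 1 ratio of the rises. The SD of that log2 ratio was 3.91 times the SD that the replicates give (2.25 against 0.58). That argues against 1 source for all 94 probes. The ratio was 6.15% at its 25th percentile and 18.7% at its 75th, so 1 source for part of the probes stays open. Position on the slide followed stage and cell type on every slide and stays open, as does a change with stage in both cell types, which was not tested further.

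The third pattern is that probes named after clones were higher than the other probes in XX relative to XY, by 0.19, 0.12, 0.23 and 0.22 (log2, germ cells at stages 33 and 35, then somatic cells) and by 0.19 on average. Without a trend on mean signal 87.7% of the mean gap was left, which argues against signal level. Without the GC trend 16.9% of it was left, in line with GC content as its source: the clone probes had a median GC content of 38.3%, against 45.0% for the others. Another split of the 6 slides gave a gap of 0.167, against 0.193 for the split by sex. Each such split puts the sexes unevenly on its sides and so holds part of any sex difference. These splits therefore cannot show whether the gap needs a sex difference. Slide or scan run and sex cannot be told apart for what is left, since no slide held both sexes.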

How the results depend on the processing

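The settings of 1 probe per distinct sequence, of probes above background on all arrays, of the arrays of 1 cell type and of the GC trend were chosen after seeing the data, as were 2 of the interactions. Of 1048 values of the 45 named results under other settings, 954 kept their direction and call, 94 kept the direction but lost the call, and 0 reversed. 27 of the 45 were called under every setting that tested them. dola:3746 in the sex by stage interaction of germ cells lost its call under 20 settings. Counts within 1.5 times the reported one are not listed. The cause was not tested where none is given.

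With normexp background correction, whose offset of 50 shrinks the differences of dim probes, the sex comparisons called 139 (germ cells, stage 35), 236 (somatic cells, stage 33) and 191 (somatic cells, stage 35). The stage comparison of somatic cells called 6383, the stage by cell type interaction 6020, sex by cell type at stage 35 5, and sex by stage 0 in both cell types (limma, 267 probes at an unadjusted p under 0.05 in germ cells and 435 in somatic cells). Quantile normalization gave 878 and 519 for the sexes in germ cells at stages 33 and 35, 30 and 0 for sex by stage in somatic and germ cells, and 23 for sex by cell type at stage 33. Without the filter on dim probes, sex in germ cells at stage 35 gave 165, and sex by stage gave 0 in germ cells and 6 in somatic cells.

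The deposited table without scaling called 62 and 13 for the sexes in germ cells (stages 33 and 35), 39 and 27 in somatic cells, 968 and 4879 for stage in germ and somatic cells, and 3127 for stage by cell type. It called 0 and 5 for sex by stage in germ and somatic cells, and 4 and 5 for sex by cell type at stages 35 and 33. The median of all probes for germ minus somatic cells was 0.18 as reported, -0.33 with normexp, -0.26 without the filter and 1.22 without scaling. Without scaling that median was -0.48, -0.12, -0.29 and -0.31 in the sex comparisons, against -0.04, -0.04, -0.03 and -0.02. The share of calls higher at stage 35 was 50.1% in somatic cells as reported, 39.5% under quantile normalization and 40.1% among probes seen on all arrays. For the sexes in germ cells at stage 35 the share higher in XX was 41.1%, against 53.6% without the GC trend, 50.7% under quantile normalization, 15.4% without scaling and 18.8% on the arrays compared. In somatic cells at stage 33 it was 35.1%, against 46.2% without the GC trend, and at stage 35 35.9%, against 18.5% without scaling.

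Fitted on the arrays of the groups compared, with fewer arrays to estimate the spread, the sexes gave 3763 and 32 in germ cells, 3 and 5 in somatic cells, and stage in germ cells gave 9267. Sex by stage in somatic cells gave 2, and sex by cell type 9 at stage 35 and 23 at stage 33. Sex by stage in germ cells also gave 1, but another probe. On the arrays of 1 cell type the sexes gave 2026 and 1292 in germ cells and 51 and 46 in somatic cells. At the same sex and stage the spread was larger on somatic arrays.

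Among the 12735 probes above background on all arrays, where fewer were tested, germ against somatic cells gave 11553, the sexes in germ cells 828 and 460, stage by cell type 6381, sex by stage 0 in both cell types, and sex by cell type 4 and 7 at stages 35 and 33. Sex by stage in germ cells also gave 0 with a trended and robust prior, without the GC trend, and with slide or scan day as a block. Slide as a block gave 6 for sex by stage in somatic cells.

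Within a sex a replicate number is a slide. In no comparison did every pair of the same number correlate above 0.1, but the 3 pairs of stage 33 XX germ and somatic arrays from the same slide did (0.161, 0.146 and 0.215). With replicate number as a block sex by stage in germ cells gave 0, and the other counts stayed within 1.5 times.

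Leaving out arrays in turn gave 19919 to 20095 for germ against somatic cells, 4903 to 5747 and 9936 to 11541 for stage in germ and somatic cells, and 9017 to 10179 for stage by cell type. Sex in germ cells at stage 33 ranged from 131 to 387: it was 149 and 226 without XX replicates 1 and 2, and 131, 190 and 211 without XY replicates 1, 2 and 3. At stage 35 it ranged from 78 to 381: 92 and 126 without XX replicates 1 and 2, and 78, 109 and 146 without XY replicates 1, 2 and 3. Sex in somatic cells at stage 33 ranged from 774 to 2415: 1063 without XX replicate 2, and 774 and 1075 without XY replicates 1 and 3. At stage 35 it ranged from 407 to 2886: 2886 without XX replicate 3 and 407 without XY replicate 1.

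Sex by stage in germ cells ranged from 0 to 1, with 0 when any of 9 of the 12 arrays was left out (all but stage 33 XX replicate 3, stage 33 XY replicate 2 and stage 35 XY replicate 1). In somatic cells it ranged from 8 to 56. It gave 33, 9 and 56 without stage 33 XX replicates 1, 2 and 3, and 8 without stage 33 XY replicate 3. At stage 35 it gave 33 and 32 without XX replicates 2 and 3, and 8 and 40 without XY replicates 2 and 3. Sex by cell type at stage 35 ranged from 12 to 129: 12 without germ XX replicate 1, 13 without germ XY replicate 2, and 129 and 35 without somatic XX and XY replicate 3. At stage 33 it ranged from 11 to 48: 48 and 47 without somatic XX replicates 1 and 3.

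The planned repeats for gene lists and symbols were not run, since no probe has a gene name. Signal over background limits the dim probes: 3903 probes were above background on no array, and the lowest signal above background ranged from 0.33 to 2.80 (log2) between arrays.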

Other observations

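Chosen after the data were examined, groups of probes by the prefix of their names were tested in limma with camera, 8 groups in 12 comparisons (96 tests), adjusted within each comparison. With a preset correlation between probes of 0.01, 36 had an adjusted p under 0.05, in 7 comparisons. With the correlation estimated from the arrays 4 had, the group dola in each of the 4 sex comparisons, lower in XX than the other probes (adjusted p of at most 0.00143), and the lowest of all others was 0.146. The test allows for correlation within the tested group and not among the probes it is set against. The group dola held 17459 probes at an estimated correlation of 0.0075, set against clone groups at 0.070 to 0.132. Its p-values leave that correlation out, so they are no firmer than those of the clone groups. The GC content of the probes differs between these groups, as given above for the clone probes.

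A few sets of probes followed detection alone. Well above background on every stage 35 somatic array and no stage 33 somatic array were 174 probes, and the reverse held for 58. In germ cells these numbers were 3 and 9. Above background on all XY and no XX arrays were 8 probes in somatic cells and 10 in germ cells, and on all XX and no XY arrays 1 and 0. No probe separated all 12 XY from all 12 XX arrays in this way (0 in either direction).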
